A study of Mus musculus with 2 samples.

How the data were processed

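Gene expression was measured in dorsal root ganglion (DRG) neurons of mice carrying the AND T cell receptor transgene, with 1 array for Dock8+/- and 1 array for Dock8-/-. Total RNA was isolated with Isogen and cRNA was amplified and labelled with Cy3 using a low-input kit, per the labels' protocols. Both arrays lay on the same slide, per the file headers. No batch split was therefore available within a group, and no difference between the groups has a replicate check.

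The deposited scanner files give the intensity of each spot on a linear scale, made by the authors with Agilent Feature Extraction. The file headers name version 10.7.1.1, whereas the submitters' processing notes name version 9.5.1.1. Per the file headers, the processed intensity is detrended, and dim spots carry a small surrogate value above 0. The deposited value table holds intensities on a linear scale that were found to be quantile normalised: 98.9% of the sorted values were exactly equal in both columns (tolerance 0), the largest gap between sorted values was 0.665, and each column had a median of 27.9. Its direction is that of intensity, and its log2 values had a correlation of at least 0.999 with those of the matching scanner file across probes. With scale and direction found in this way and no centring between genes seen, none of the 3 stays unknown. It served as an alternative, and 0 of its value columns were left unused.

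From the scanner files, log2 processed intensity was averaged over the spots of a probe, and each array's 75th percentile over its non-control probes was subtracted. Non-uniform spots were left out (3 on the Dock8+/- array and 1 on the Dock8-/- array), and no non-control spot was saturated on either array (0 on each). Probes were named by RefSeq accession through a table of the assembly GRCm38.p6, which was used for names only. In all, 32994 probes were named by accession, 10224 by a symbol in that table and 520 by an older symbol, while 12867 kept the name in the scanner file. A gene with several probes took the probe with the highest mean on both arrays. A gene counted as measured when that probe was well above background on both arrays, which held for 18649 of 37008 gene names. Where no probe of a gene was well above background on 1 array and at least 1 was on the other, the difference is a lower bound, taken from the bright value against the higher of the dim probe's own value and the lowest signal among probes well above background on the other array. Probe positions are those of the files, on mouse build mm9. Exon and UTR annotation of that build was not used here.

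With 1 array per group no test, p-value or standard error between groups exists, and a 2-fold difference was used as a description of size. The 37 gene lists and the rule for named genes were fixed before the data were examined. For each list with at least 4 measured genes (35 lists), the median log2 difference was placed among 10000 random lists of the same size, matched on mean signal in 20 bins. A list was said to lie outside the random range when its median was among the lowest or the highest 2.5% of these, which holds for 1.75 of 35 random lists on average. These percentiles describe the 2 arrays and are not p-values. Further lists, named in the closing section, were written after the first values had been seen, and their members with unseen values were kept apart.

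The rule for named genes took the 12 genes with the largest and the 12 with the smallest difference among measured genes with a mean signal at or above the median, leaving out saturated probes and uncharacterised symbols. It also took the 5 largest bounds in each direction, a set of genes of itch and of DRG neurons, members of the neuropeptide and itch receptor lists at least 1.5-fold apart, and up to 4 members with the largest difference from each other list. Sex-linked genes and spike-ins served as checks. A gene outside the rule is said to have been chosen after its values were seen, and 2 genes that the rule takes are not reported here.

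Alternatives were other scalings (75th percentile or median of probes detected on both arrays, quantile normalisation, loess with a span of 0.3, and spike-in scaling), normexp background correction with an offset of 50, the authors' deposited value table, the mean of a gene's probes, thresholds of 1.5-fold and 3-fold, other filters on dim probes, random lists without matching, removal of saturated spots, and another detection flag. Leaving out probes with at least 4 GA or 4 GAA units was added after seeing the data. A gene's value counted as moved when it shifted by at least 0.0691 on the log2 scale, the SD expected for a difference of single spots, and a list median when it shifted by at least 1 SD of its random lists.

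Spot error was small. The 299 probes with 10 spots that were well above background on each array had a root mean square SD of 0.0438 on the Dock8+/- array and 0.0535 on the Dock8-/- array. Probes of one gene differed more, with a median SD of 0.409 in their log2 differences over 6234 genes. Neither value covers differences between animals.

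The scripts were tested on simulated data for this comparison, with 200 genes changed and a noise SD of 0.409 in the log2 difference, over 21420 measured genes. All 50 genes changed 4-fold and all 50 changed 8-fold passed 2-fold on the right side, as did 64.0% of genes changed 2-fold and 24.0% of genes changed 1.5-fold. Of 21220 unchanged genes, 1.53% passed 2-fold in either direction. Of 200 unchanged lists, 3.5% fell outside the random range, which was drawn from the same unchanged genes. The changed genes were taken from measured genes with a mean signal above the median, and every probe had the same noise. Measured genes of the 2 real arrays had differences with an SD of 0.78. The lower detection on the Dock8-/- array was not simulated, so these rates need not hold for the real arrays, least of all for dim genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used, with limma 3.58.1 in R 4.3.3.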

Results

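DRG neurons hold the sensory cell bodies that carry itch and pain from the skin. DOCK8 is a guanine nucleotide exchange factor of immune cells, and the labels give the Dock8-/- mouse a high and the Dock8+/- mouse a low level of interleukin-31 (IL-31), a cytokine that causes itch. The comparison asked which transcripts differ in DRG neurons between these mice. With 1 array per genotype, every difference given here is between 2 arrays, has no replicate check and cannot be separated from differences between samples of 1 genotype. Of the non-control probes, 56.9% were well above background on the Dock8+/- array and 50.7% on the Dock8-/- array. The 75th percentile of processed intensity was 303.8 and 145.6, respectively, so dim transcripts were read with less certainty in the Dock8-/- sample. The number of arrays limits the precision. Directions are relative to the 75th percentile of each array. On the scale of spike-in transcripts all genes were shifted by -1.84, of 44 named genes at least 2-fold higher 21 stayed above 0, and Il31ra, Osmr and Nppb were lower.

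Dock8 itself gave no check of the labels. Of its probes, 1 was well above background on the Dock8+/- array, with a processed intensity of 20.5, and its intensity on the Dock8-/- array was 6.87, not well above background. The other Dock8 probes were not well above background on either array. Which part of the gene was deleted is not given in the sources used here, and a probe outside that part checks nothing. The Il31 probe was not well above background on either array.

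Tac2, which encodes neurokinin B, was 67.0-fold higher in the Dock8-/- sample, the largest difference of 18649 measured genes. Its scaled log2 signal was -3.85 in Dock8+/- and 2.22 in Dock8-/-, with processed intensities of 21.1 and 677.2, the first close to 17.4, the lowest among probes well above background on that array. The log2 difference of 6.07 was 3.99 under normexp background correction and 4.23, or 18.8-fold, under spike-in scaling. Neuropeptide genes as a group were higher in the Dock8-/- sample. The 17 measured members of the list had a median log2 difference of 0.68, at the 100th percentile of matched random lists, and 14 of them were higher. Nts, encoding neurotensin, was 2.60-fold higher, Nppb, encoding the itch transmitter natriuretic polypeptide b, 2.22-fold higher, and Cck, encoding cholecystokinin, 2.07-fold higher. The Tac2 value rests on a single probe, for transcript NM_001199971, with the sequence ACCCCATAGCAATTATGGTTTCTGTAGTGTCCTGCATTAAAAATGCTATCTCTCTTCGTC at positions 127168740 to 127168799 of chromosome 10 (mm9).

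Other neuropeptides differed less or were read on 1 array only. Penk, the enkephalin precursor, had a log2 difference of 0.99, Npff 0.89, Adcyap1 0.77, Vgf 0.76, Scg2 0.68 and Cartpt 0.59. Tac1, which encodes substance P, had a difference of 0.37 and Sst, encoding somatostatin, 0.29. Calca, the gene for calcitonin gene-related peptide, lay at -0.02 on its brightest probe and at 0.55 on the other. Chga was 1.77-fold lower. Pdyn, encoding prodynorphin, was at least 9.61-fold higher and Npy, encoding neuropeptide Y, at least 7.28-fold higher, each well above background on the Dock8-/- array only. Grp was not well above background on either array. Genes of the spinal cord list were also higher in the Dock8-/- sample, with a median difference of 0.97 over 14 measured genes.

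**Figure D1:**
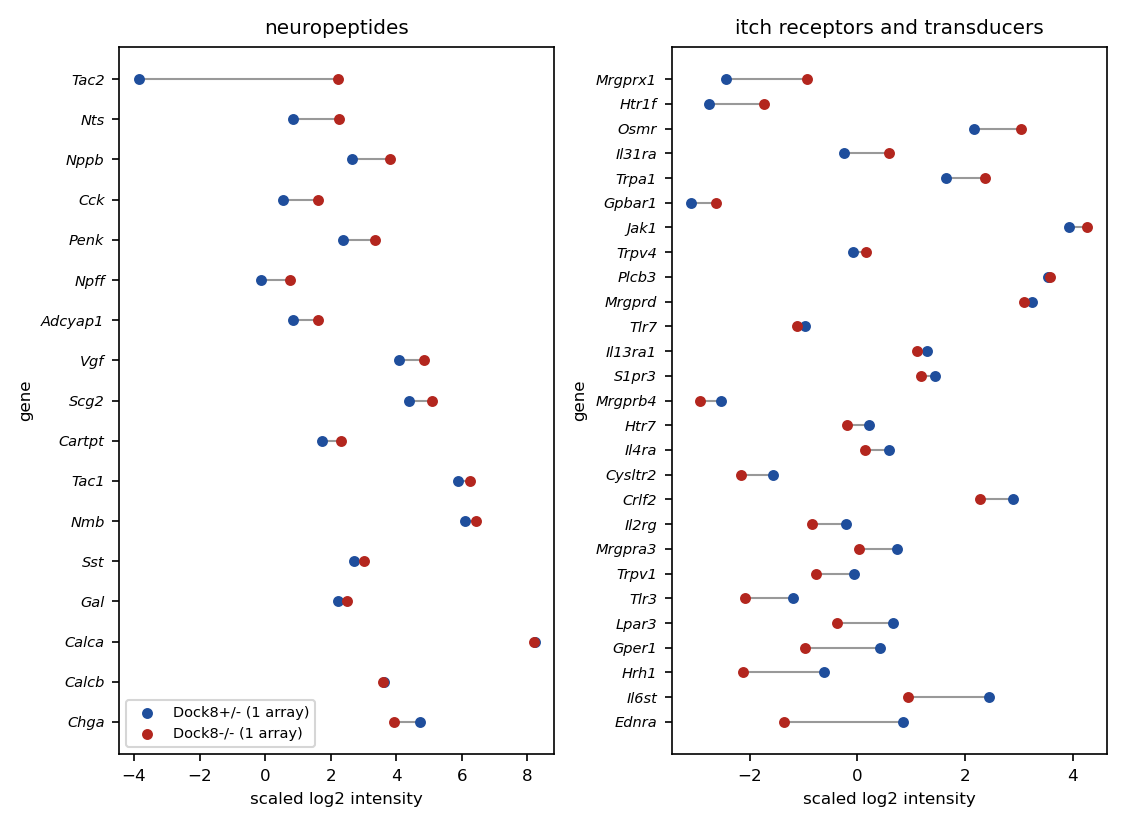
Scaled log2 intensity (x axis) of the measured neuropeptide genes (left) and itch receptor and transducer genes (right), 1 gene per row, with the Dock8+/- array in blue and the Dock8-/- array in red. Tac2 has the longest line, from -3.85 to 2.22, and itch receptor genes lie on both sides.

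The IL-31 receptor genes were higher in the Dock8-/- sample, while the itch receptor list as a whole was lower. Il31ra was 1.78-fold and Osmr, encoding the partner chain of the IL-31 receptor, 1.83-fold higher, below the 2-fold size. All 4 Il31ra probes measured on both arrays were higher, with differences from 0.70 to 1.53, and all 3 Osmr probes, from 0.87 to 1.95. The brightest Il31ra probe lies at 113312329 to 113312388 of chromosome 13 and that of Osmr at 6763686 to 6763745 of chromosome 15 (mm9). The 27 measured genes of itch receptors and transducers had a median difference of -0.39, at the 0.47th percentile of random lists, with 2 genes at least 2-fold higher and 5 at least 2-fold lower. Fibroblast, macrophage and MHC class II genes were lower beside them, with medians of -1.72, -1.33 and -2.22. Ednra, an endothelin receptor, was 4.66-fold lower, Hrh1, a histamine receptor, 2.84-fold lower and Gper1 2.64-fold lower. Il6st, encoding gp130, was 2.85-fold lower on its brightest probe, whereas its other probe gave 0.22. Mrgprx1 was 2.84-fold and Htr1f, a serotonin receptor gene, 2.04-fold higher. Lpar3 was 2.05-fold lower. Trpa1, an irritant-gated channel, differed by 0.74 (probes from 0.21 to 1.38), Trpv1, the capsaicin receptor, by -0.70, Mrgpra3 by -0.70 and Mrgprd by -0.14.

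Markers of DRG neuron classes separated little. NP3 pruriceptor markers, the class that carries Il31ra and Nppb, had a median difference of 0.58 over 12 genes, at the 99.7th percentile of random lists. That list shares Nppb, Sst, Il31ra, Osmr, Cysltr2, Htr1f, Nts and Jak1 with the neuropeptide and itch receptor lists and is not independent of them. Medians were 0.00 for NP1 and NP2 non-peptidergic markers, 0.20 for peptidergic nociceptor markers, 0.22 for nociceptor ion channels, 0.08 for cold and C low-threshold markers and -0.17 for large myelinated neuron markers, all within the random range. Pan-neuronal genes had a median of 0.03 over 21 genes and housekeeping genes 0.14 over 14 genes. Among channels, Scn9a, a sodium channel gene, was 2.14-fold higher, and Cacna2d1 2.43-fold on its brightest probe, with probes from -0.43 to 1.91. Pou4f1 was 8.54-fold higher on its brightest probe, which holds a GA repeat, and its other probes gave 0.09 and 0.75.

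Nerve injury genes were higher in the Dock8-/- sample, and immediate early genes were lower. All 14 measured genes of the injury list were higher, with a median difference of 0.90 at the 100th percentile of random lists, and 5 were at least 2-fold higher. The injury list shares Gal, Npy, Nts, Vip and Crh with the neuropeptide list and Atf3 and Jun with the immediate early list. It is not independent of them. Sox11, a transcription factor of regrowing neurons, was 3.28-fold higher, Flrt3 was 2.21-fold higher, and Atf3, named after its value was seen, differed by 0.85. Satellite glia genes were higher beside them, with a median of 0.57. Of 20 immediate early genes, 8 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.68 at the 0th percentile of random lists. Egr1 was 6.92-fold, Nr4a1 4.55-fold and Fos 3.07-fold lower. Genes of the gp130, JAK and STAT response had a median of 0.26 over 21 genes at percentile 97.2, within the random range but above it under quantile normalisation, loess, normexp, the authors' value table and removal of repeat probes. Lcn2 had a difference of 1.62 there, and Junb was 2.96-fold lower.

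Genes of macrophages and antigen presentation were lower in the Dock8-/- sample, as were fibroblast genes, with a median of -1.72. All 7 measured genes of MHC class II presentation were at least 2-fold lower, with a median of -2.22, and H2-Ab1 was 12.1-fold lower. Macrophage genes had a median of -1.33 over 19 genes, of which 13 were at least 2-fold lower, including Lyz2, encoding lysozyme, at 7.33-fold, Adgre1 at 3.77-fold and C1qa at 3.61-fold. Interferon response genes had a median of -0.44, with Oas2 5.51-fold and Isg15 3.57-fold lower. Cytokines and chemokines had a median of -0.60, which lay within the random range under normexp background correction, with Ccl2 3.95-fold lower and Ccl17 3.61-fold higher. Mast cell proteases Mcpt4 and Cma1 were at least 27.9-fold and at least 19.6-fold lower, and Retnla, a marker of alternatively activated macrophages, at least 59.7-fold lower. Neutrophil genes went the other way, with a median of 0.64 over 11 genes at the 99.6th percentile but within the random range under loess, and Ngp was 4.84-fold higher. That median leaves out 2 members at least 2-fold lower and 1 at least 2-fold higher by their bound. T and NK cell genes had a median of 0.47 over 7 genes, within the random range.

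Genes of muscle, cartilage and connective tissue were lower in the Dock8-/- sample. The skeletal muscle list had the lowest median of any list, -3.66 over 6 measured genes. By their bound, 6 more, read on the Dock8+/- array only, were at least 2-fold lower. Tnnt3 was 16.2-fold, Tnnc2 15.3-fold and Tnni2 12.8-fold lower. Cartilage and bone genes had a median of -2.92 over 5 genes, with Comp 18.8-fold lower. Of 14 fibroblast and connective tissue genes, 12 were at least 2-fold lower, with a median of -1.72, and Col3a1, a fibrillar collagen gene, was 9.25-fold lower on its brightest probe. Its probes ranged from -3.21 to -0.42. Erythroid genes had a median of -1.15 over 7 genes. Endothelial and pericyte genes had a median of -0.31 over 14 genes, within the random range but below it under normexp background correction. The largest lower values by the naming rule were those of H19 (40.0-fold), Ecrg4 (28.5-fold), Pf4 (21.9-fold), Comp, Sfrp4 (18.4-fold), Myh8, Tnnc2, Pi16, Lypd2, Prelp, Tnni2 and H2-Ab1.

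Glial genes differed in direction. Satellite glia genes had a median of 0.57 over 16 genes, at the 99.9th percentile, with Sox2 2.88-fold and Kcnj10 2.02-fold higher and Fabp7 4.63-fold lower. Of the spinal cord list, Gfap was 8.42-fold, the glutamate transporter gene Slc1a2 3.79-fold and Aqp4 2.56-fold higher, whereas Slc6a5, a glycine transporter gene named after its value was seen, was 2.29-fold lower. Schwann cell and myelin genes had a median of -0.12 over 17 genes. The peripheral myelin genes Prx and Pllp were 2.42-fold and 2.81-fold lower.

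**Figure D2:**
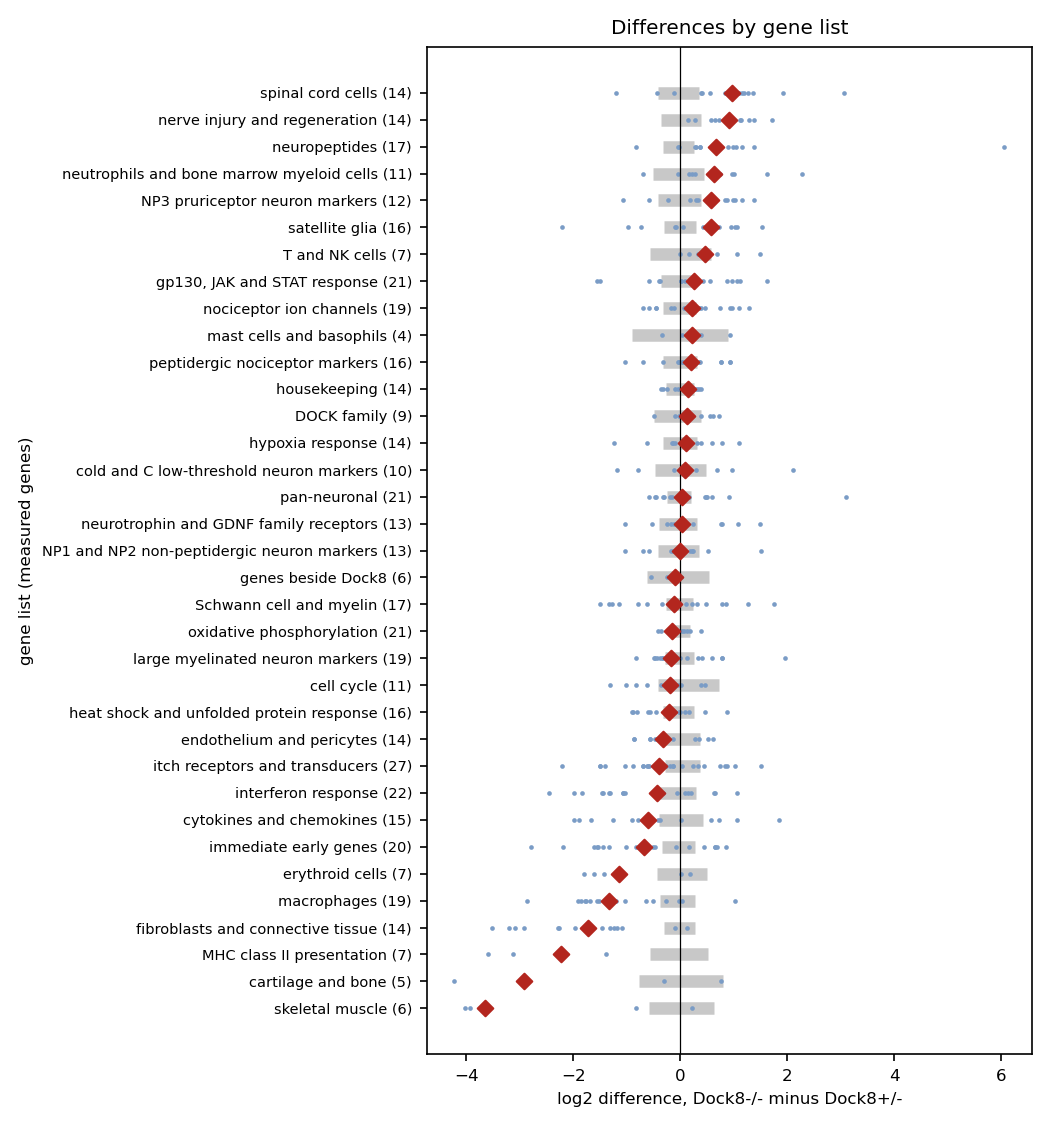
Log2 difference, Dock8-/- minus Dock8+/- (x axis), of each gene list with at least 4 measured genes (y axis, number of measured genes in brackets). Blue dots are genes, red diamonds list medians and grey bars the medians of matched random lists without the outer 2.5% on each side, with skeletal muscle lowest at -3.66 and spinal cord cells highest at 0.97.

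Over all genes, 1694 of 18649 were at least 2-fold higher in the Dock8-/- sample and 1311 at least 2-fold lower. A further 510 genes were at least 2-fold higher by their bound and 449 lower, led by Dsg1b (at least 19.4-fold higher) and Retnla. The 510 were among 515 genes read on the Dock8-/- array only, and the 449 among 2545 read on the Dock8+/- array only. The lowest signal among probes well above background was 17.4 on the Dock8+/- array and 16.1 on the Dock8-/- array. The 75th percentiles used for scaling were 303.8 and 145.6. After scaling this floor was therefore lower on the Dock8+/- array. By construction this raises the bounds of higher genes and reduces those of lower genes, so the 510 and 449 cannot be compared with each other. The counts of 510 and 449 became 178 and 1260 under loess, 206 and 39 under normexp and 38 and 2511 under spike-in scaling. Of the 12 largest higher values by the naming rule, 10 came from probes with a purine repeat, namely Syn3, Tbx22, Cd300lf, Mrgprg, Cdcp1, St6galnac1, Opcml, Trp53rkb, Rabgap1 and Klra1. Probes of Syn3 ranged from -0.26 to 4.10 and those of Trp53rkb from -1.36 to 3.40, whereas Tbx22, Cd300lf, Mrgprg, Cdcp1, St6galnac1 and Klra1 each had 1 measured probe. The remaining 2 were Plin4, a lipid droplet gene, at 18.9-fold and Ddc, encoding an enzyme of monoamine synthesis, at 11.6-fold. Without repeat probes, an alternative added after seeing the data, 1615 genes were higher and 1313 lower. Spike-in scaling gave 58 genes at least 2-fold higher and 16217 lower, and normexp background correction 703 and 865.

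**Figure D3:**
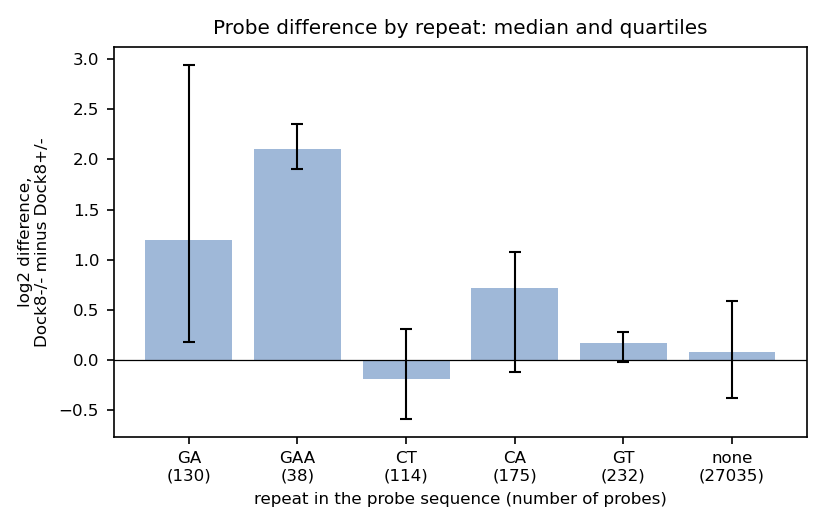
Median log2 difference of probes, Dock8-/- minus Dock8+/- (y axis), by repeat in the probe sequence (x axis, number of probes in brackets), with bars from 0 and whiskers at the quartiles. Probes with GA repeats had a median of 1.19, GAA repeats 2.10, CA repeats 0.72 and probes without a repeat 0.08.

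**Figure D4:**
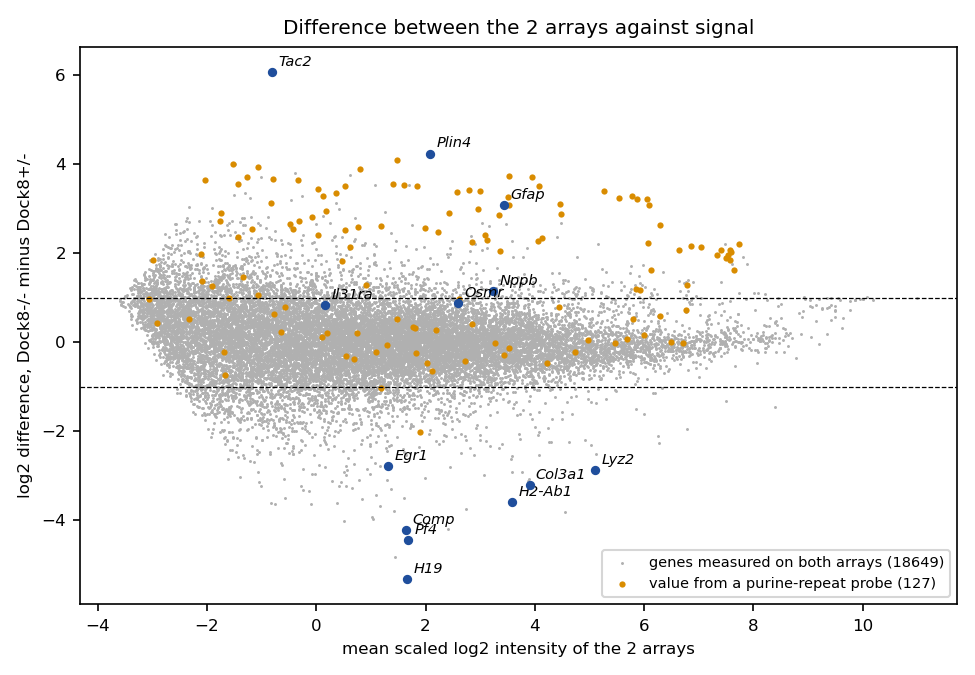
Log2 difference, Dock8-/- minus Dock8+/- (y axis), against the mean scaled log2 intensity of both arrays (x axis) for the 18649 measured genes. Dashed lines mark a 2-fold difference, orange points are the 127 genes whose value comes from a purine-repeat probe, and labelled blue points are genes described in the text, with Tac2 at the top.

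Ddx3y, Eif2s3y and Uty were not well above background on either array, Kdm5d differed by -0.45, and Xist differed by 0.21. The 3 Dock8 neighbours Kank1, Vldlr and Dmrt1 differed by -0.24, -0.09 and -0.09 on their brightest probes, although probes of Kank1 ranged up to 2.75, and 0 of 6 measured genes beside Dock8 were 2-fold apart (list median -0.09). Hypoxia, heat shock, oxidative phosphorylation, cell cycle, neurotrophin receptor, DOCK family, and mast cell and basophil lists had medians of 0.12, -0.20, -0.16, -0.19, 0.02, 0.12 and 0.21, all within the random range. The mast cell and basophil median covers 4 measured genes only. It leaves out 3 members read on the Dock8+/- array only, each at least 2-fold lower by its bound. The B and plasma cell list had 2 measured genes and a median of 1.21, with Ms4a1 4.49-fold higher. Another 2 of its genes, read on the Dock8+/- array only, were at least 2-fold lower by their bound.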

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

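Removal of purine-repeat probes was chosen after seeing the data, and with 1 array per group no replicate could be left out. No paired analysis was possible because each group held 1 array and the results come from no test. Scaling to another percentile, the median or spike-ins moves all genes by a constant, so it cannot move a list among random lists. Of the 16 lists outside the random range, 16 kept their side under quantile normalisation, the authors' value table, the mean of probes, removal of repeat probes and random lists without matching, while neutrophil genes left it under loess and cytokines under normexp. The gp130, JAK and STAT list lay above the range under quantile normalisation, loess, normexp, the value table and removal of repeat probes, and endothelial genes lay below it under normexp. Of 101 named genes at least 2-fold apart, 79 remained so under normexp, 90 without repeat probes and 94 with the mean of probes. Under the other scalings and the value table, 99 or more remained, but under spike-in scaling 72. Spike-in scaling shifts all genes by -1.84, so genes at least 2-fold lower could not fail there. Of the 44 at least 2-fold higher, 15 stayed so on that scale. Tac2 was lowest under normexp, at 3.99, and lay at 4.23 on the spike-in scale. Without repeat probes Syn3 turned to -0.26 and Trp53rkb to -1.36, since the repeat probe had been their brightest. Counts moved more, and apart from thresholds and filters, which change them by construction, the cause was not tested. Against 1694 higher and 1311 lower, normexp gave 703 and 865, spike-in scaling 58 and 16217, 1.5-fold 3890 and 3147, 3-fold 486 and 424, no filter on dim probes 5437 and 2758, and a mean signal at or above the median 466 and 475. Well above background on at least 1 array gave 2216 and 2578. The Dock8-/- array alone read 515 genes and the Dock8+/- array alone 2545, of which 510 and 449 were at least 2-fold apart by their bound. The 510 and 449 depend on each array's detection floor after scaling, which lay lower on the Dock8+/- array, and cannot be compared with each other. Against these 510 and 449, loess gave 178 and 1260, normexp 206 and 39, spike-in scaling 38 and 2511, and the other detection flag 2014 higher. The share of higher among 2-fold genes was 56.4%, but 43.6% under loess, 44.8% under normexp, 0.356% under spike-in scaling, 46.2% with well above background on at least 1 array and 49.5% with a mean signal at or above the median. Signal over background limits dim genes most on the Dock8-/- array, where spike-ins were 1.71-fold brighter and the 75th percentile of the sample 2.09-fold lower.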

Other observations

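The tests of lower signal, of binding through a repeat and of dim signal were chosen only after the results were seen. Genes induced by glucocorticoids stood out beyond the lists of the report. Plin4, named by the rule, and Zbtb16 and Sgk1, chosen after their values were seen, were 18.9-fold, 6.22-fold and 4.87-fold higher in the Dock8-/- sample. A list of glucocorticoid-responsive genes was then written, and 17 of its members had values not yet seen. Of these, 12 were at least 2-fold higher and 0 at least 2-fold lower, among them Hif3a (3.14 on the log2 scale), Pdk4 (2.19), Fkbp5 (2.08, probes from 0.94 to 2.71) and Mt1 (1.91, other probe 0.26), while Sult1a1 lay at -0.85. Their median of 1.28 was at the 100th percentile of matched random lists. Among these 17, Tsc22d3 lay at 0.48, Fam107a, at 1.13, was read by a CA-repeat probe, and Per1 is also a clock gene. Of the other list members, seen before, Mt2 lay at 2.20 and Lcn2 at 1.62, but Cebpd at 0.29 and Dusp1 at -0.52. A candidate explanation is higher glucocorticoid exposure or stress of the Dock8-/- mouse, which with 1 mouse or pool per genotype need not follow from genotype.

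Clock genes, chosen after Dbp was seen at -2.91, went both ways, with Nr1d1 at -1.75, Arntl at 2.67 (probes from -0.03) and Cry1 5.65-fold higher, but also Usp2 2.82-fold higher, Bhlhe41 at 1.12 and Per1 at 0.74, which are in phase with Dbp. Sampling at another time of day may contribute to this. The 10 unseen genes in phase with Dbp had a median of 0.00 (0.0001), which met the bound set beforehand against this explanation by less than the spread of random lists (-0.48 to 0.43). That such a gap decides nothing was settled after the value was seen. The 5 genes of opposite phase had a median of 0.68, and time of day stays open.

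Tac2 and other dorsal horn peptides were higher in the Dock8-/- sample. For Tac2 alone, scaling or background correction is argued against as the whole cause, since its lowest difference over those alternatives was 3.99. A constant shift, such as the -1.84 of spike-in scaling, could not have undone a difference of 6.07. Pdyn, Npy and the other peptides were not part of this test. A deviant probe stays open, because the array held 0 other Tac2 probes well above background, although the probe has no purine repeat. Spinal cord tissue in the sample may contribute, since 30 measured central-list genes not seen before, all above background in both samples, had a median of 0.37, at the 99.5th percentile of random lists. Among these, only oligodendrocyte genes lay outside the random range by themselves, at percentile 99.9. Astrocyte genes lay at percentile 96.2 and dorsal horn neuron genes at 36.5. Unseen dorsal horn neuron genes had a median of 0.04 beside 0.86 for oligodendrocyte and 0.33 for astrocyte genes. All 17 measured dorsal horn genes, seen ones included, had a median of 0.33 (5 at least 2-fold higher, 3 lower). By their bound, 6 more, read on the Dock8-/- array only, were at least 2-fold higher. On the other array only, 0 were at least 2-fold lower by their bound. The lower detection floor of the Dock8+/- array after scaling favours bounds in that direction. The abundant Bcan and Cldn11 lay at 0.05 and 0.19 and Slc6a5 and Slc32a1 at -1.20 and -0.44, so spinal cord tissue stays open. An effect of genotype or IL-31 stays open, untested.

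Connective tissue, muscle and macrophage genes were lower in the Dock8-/- sample. Random lists of the same signal were not as low as fibroblast genes, whose median of -1.72 lay below the 2.5th percentile of those lists, -0.31. That comparison is the one that showed the pattern, and muscle and macrophage genes were not part of it. It therefore decides nothing further on lower overall signal. Less tissue around the ganglia may explain the pattern, with no sort of neurons given in the sources used here: 28 measured genes of surrounding tissue not seen before had a median of -1.21, with sheath and fibroblast genes at -1.78 (the abundant Igfbp6 at -1.96 and Timp2 at -0.57, with Gpx3 at -0.41 and Thbs4 at -0.06) and muscle genes at -0.45, where Ttn (0.75), Tnni1 (0.59) and Mybpc1 (1.03) went the other way. The bounds set beforehand were for both lists together. Muscle genes alone lay narrowly on the side of these bounds that goes against less muscle around the ganglia. Their median was nonetheless at percentile 1.59 of matched random lists. It leaves out 2 muscle genes read on the Dock8+/- array only and at least 2-fold lower by their bound, against 0 at least 2-fold higher by theirs. Muscle genes alone therefore decide nothing, and the pooled median rests mainly on the sheath and fibroblast genes. The macrophage genes were not part of the test of surrounding tissue, and a difference of genotype in immune cells stays open.

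Relative to the 75th percentile, probes with GA repeats were higher on the Dock8-/- array, with a median of 1.19 over 130 probes. So were 38 GAA-repeat probes (2.10) and 175 CA-repeat probes (0.72, or 0.61 above probes of the same signal). Scaling added 1.06 to every log2 difference, more than the CA-repeat median, so before scaling CA-repeat probes were not brighter on the Dock8-/- array by their median. The part of scaling in the repeat pattern was not tested. Removal of purine-repeat probes left most CA-repeat probes in. Dim signal of the probes themselves is argued against, since all but the highest 2.5% of random probe sets of the same signal had medians up to 0.18. Lower signal of the whole Dock8-/- array was not tested by this, because the matched probes share it. Material from both strands is argued against as well, because CT-repeat probes lay at -0.30 relative to probes of the same signal, although GT-repeat probes, complementary to CA, lay 0.15 above theirs. Binding through the repeat may contribute but was not settled: over 70 genes, the repeat probe exceeded the repeat-free probes by a median of 0.76 (quartiles 0.04 and 2.24), between the bounds set for and against it. No biological explanation was tested.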
